A study of Mus musculus with 6 samples.

How the data were processed

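RNA from sorted mouse skin cells was measured on 1-colour Agilent microarrays. The cells came from the epidermis of male mice that had been depilated and then treated on the skin with acetone, the vehicle, or with 7,12-dimethylbenz[a]anthracene (DMBA), a carcinogenic polycyclic hydrocarbon. Cells with high expression of a keratin 15 promoter EGFP reporter, high surface integrin alpha 6 and no surface Sca1 were collected 3 days later, and the labels call them hair follicle stem cells and hair germ. Each group held 3 samples, which the series description says came from different mice, so the spread between samples includes the spread between animals.

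Per the labels, RNA was purified with the RNeasy Micro kit and cDNA was labelled with Cy3. Whether the RNA was amplified is not given in the sources used here. Per the submitters' processing notes and the file headers, spots were read with Agilent Feature Extraction 10.7.1.1, and the probe annotation in the headers names the mouse build mm9. The scanner files hold spot intensity after the background correction of that software, per the file headers. The deposited matrix of the whole series also holds intensity on a linear scale. It was divided by each array's 75th percentile, as its column 75th percentiles from 1.004 to 1.007 showed. On the log2 scale the matrix followed the scanner values (Pearson's r across probes from 0.99992 to 0.99998). Its columns had medians of 0.162, 0.154 and 0.154 for vehicle 1 to 3 and 0.172, 0.159 and 0.16 for DMBA 1 to 3. It was used only as an alternative.

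Values were log2 processed intensities minus the log2 of each array's 75th percentile, computed over spots that are not controls, in R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table. The 3671 control spots were left out, spots flagged as outliers were treated as missing (45 probe values), and spots of the same probe were averaged. Of 55681 probes, 44955 were well above background on at least 3 of the 6 arrays, whatever their group, and were kept. The files used here carry no gene symbols, so probes were named by matching their RefSeq accession without its version to the GRCm38.p6 annotation, used for names only. A symbol was found for 28331 probes, and 27350 probes, of which 16194 carry a genomic interval as their name, stayed without one. The genes tested were the 17834 with a symbol and a kept probe. Of these, 4641 had more than 1 kept probe and were represented by the probe with the highest mean over all 6 arrays. That rule has a cost: in 1137 genes the probe in use was over 16-fold brighter than another probe of the same gene, among them 51 of the brightest 100 genes, and such probes can read other transcripts. For that reason levels are not compared between genes.

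The 75th percentile intensity was 2274 on the array of vehicle 1, 2134 on vehicle 2, 1758 on vehicle 3, 1355 on DMBA 1, 2222 on DMBA 2 and 2128 on DMBA 3. The share of probes well above background was 83.6%, 82.6% and 77.0% on the vehicle arrays and 80.9%, 69.3% and 73.5% on the DMBA arrays. The lowest value on an array was -8.62, -8.73 and -8.23 for vehicle 1 to 3 and -8.01, -7.32 and -7.79 for DMBA 1 to 3. Probes near that floor can therefore read as higher after DMBA. No spot was saturated. Vehicle 1 lay on its own slide, which was also scanned apart from the other 5 arrays, so slide and scan are the same division of the arrays. No 2 arrays held identical values. Precision is limited by the number of arrays. The median residual SD per gene was 0.65 on the log2 scale in the dimmest of 3 equal groups of genes by mean signal, 0.50 in the middle group and 0.29 in the brightest.

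DMBA was compared with vehicle with limma (lmFit and eBayes, two-sided, no covariates), and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. Where a gene was well above background on no array of a group, the difference is given as a bound. The bound sets the mean of the brighter group against a mean over the arrays of the other group. For each of those arrays it takes the lowest signal among probes well above background or the probe's own signal, whichever was higher. It leaves out the spread between arrays, so it is a limit for background only. The 23 gene lists were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 23 lists, with camera at an estimated correlation and with fry beside it. Fry was planned in its directional and its mixed form, and a list counts as called with fry by the directional form. Counts of list members adjusted over the list alone are given as such. Named genes followed a rule fixed at the same time: up to 14 genes per direction past the threshold by size of change, with groups that do not overlap and the higher group well above background throughout, filled with the genes of smallest p where fewer passed and leaving out names that are only identifiers, up to 4 members of each list past the threshold, filled to 2 with members of smallest p, and 14 genes chosen for the study's question. Genes named outside that rule were chosen after their values were seen. They are the further members of the lists, Apln, and the genes given only as examples of a list.

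The procedure was tested on simulated data with the real means and residual SDs of the 17834 genes, 200 of them changed, in 20 simulations. Each residual SD, estimated with 4 residual degrees of freedom, was taken as the true spread, so recovery on the real arrays may differ. The test at adjusted p recovered 0.597% of 2-fold changes, 33.5% of 4-fold changes and 61.8% of 8-fold changes, and the unadjusted test 66.0%, 88.7% and 95.7%. With no change simulated, 0.1 genes per simulation passed on average, and camera called 0 lists. A list of 41 genes shifted by 0.60 on the log2 scale was called in 20 of 20 simulations. Genes varied independently in all these simulations, so they cannot show how often camera calls a list whose genes vary together. On the real arrays, splits that mix the groups gave up to 3 called lists.

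Alternatives planned before the data were examined were a normexp background with offset 50, quantile and cyclic loess normalization, the deposited matrix, 3 other filters on dim probes, the mean of a gene's kept probes, all kept probes tested apart, an intensity trend with robust eBayes, array weights, the replicate number, slide or scan as a block, each array left out in turn, other set tests and other thresholds. The normexp alternative was run on the median spot intensity, since the files hold no mean spot intensity. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.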

Results

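Gene expression was measured in hair follicle stem cells and hair germ cells, the cells at the base of the resting follicle from which a new hair grows, 3 days after mouse skin was treated with vehicle or with DMBA. Each group held 3 mice with 1 array each. Arrays of the same group correlated across genes with Pearson's r from 0.937 to 0.951 and arrays of different groups with r from 0.934 to 0.948, so treatment did not separate the arrays as wholes. The sort markers were well above background on every array. Krt15 lay at 5.81 ± 0.10 (SD, n = 3) in vehicle and 6.01 ± 0.42 in DMBA on the log2 scale relative to the 75th percentile of each array. Itga6, the integrin of the gate, lay at 2.52 ± 0.14 and 2.33 ± 0.53.

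The series concerns the fates of stem cells under stress in hair greying and melanoma, and the comparison asked which genes of these follicle cells, a niche of melanocyte stem cells, differ after DMBA. By camera at the preset correlation, the list with the smallest adjusted p was that of the target genes of p53, the transcription factor activated by DNA damage (adjusted p = 3.72e-09; adjusted p = 0.384 with an estimated correlation). The order of the lists depended on the test: with fry the xenobiotic list had an adjusted p of 0.0551 and the p53 list 0.162. Of the 41 measured genes of that list, 32 were higher and 9 lower after DMBA, with a median log2 fold change of 0.60. Cdkn1a, which encodes the cell cycle inhibitor p21, was 3.69-fold higher. The keratins Krt6a and Krt6b, which keratinocytes make after wounding, were 3.85-fold and 2.72-fold higher. Kitl, the ligand of the receptor KIT on melanocytes and their stem cells, was 1.84-fold higher, a difference that did not pass the test over all genes.

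No gene passed the threshold over all 17834 genes tested with limma (0 higher, 0 lower; smallest adjusted p = 0.438). At unadjusted p under 0.05, 488 genes were higher and 445 lower, where 891.7 would pass by chance alone. The 3 DMBA values all lay above or all below the 3 vehicle values in 870 and 922 genes, respectively, and chance alone gives 10% of genes tested. With no filter on dim probes, 1259 of 21354 genes were higher and 455 lower at unadjusted p under 0.05. Without DMBA 1 the number of genes lower at unadjusted p was 728, and without vehicle 2 1 gene passed the threshold, Apln, the ligand of the apelin receptor, well above background on 1 vehicle array (log2 fold change 6.40, adjusted p = 0.0335 there, and 4.80 with adjusted p = 0.751 over all arrays). Fry's mixed test asks whether the members of a list differ in either direction, and 8 of the 23 lists passed it. Adjusted p was 0.000162 for p53 targets and for NRF2 targets, 0.00210 for wound and stress genes and for fibroblast markers, and 0.00252 for hair germ signalling. It was 0.00965 for senescence genes, 0.0228 for arachidonic acid metabolism and 0.0280 for xenobiotic metabolism.

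The list of p53 targets and DNA damage response genes rose as a set (camera adjusted p = 3.72e-09 with the preset correlation). The call was lost with an estimated correlation (adjusted p = 0.384), and with fry, which asks whether the genes move 1 way on balance, adjusted p was 0.162. Of its members, 0 passed over all genes and 8 passed when adjusted over the list alone, all higher after DMBA and each with all 3 DMBA arrays above all 3 vehicle arrays. Besides Cdkn1a (log2 fold change 1.88, SE 0.31; 2.96 on its other probe), they were Ccng1, which encodes cyclin G1 (1.79, SE 0.35), and the death genes Pmaip1 (1.99, SE 0.47) and Ei24 (0.96, SE 0.22). The others were the cell cycle brakes Btg2 (1.16, SE 0.31) and Rprm (3.55, SE 0.82), the receptor gene Eda2r (2.03, SE 0.54) and Dcxr, an enzyme of sugar metabolism (1.92, SE 0.48). Plk3, Polk, Sesn2 and Trp53inp1 had values of 2.19, 1.16, 1.04 and 0.99 and did not pass. Rrm2b, a ribonucleotide reductase subunit that p53 induces, went the other way, with a value of -0.74 (SE 0.25) and all 3 DMBA arrays below all 3 vehicle arrays, and did not pass either. Plk3 was well above background on 1 vehicle array. Other well-known targets lay near 0: Mdm2, the ligase that degrades p53, had a log2 fold change of 0.16 (SE 0.39), Bax 0.12 (SE 0.20), Gdf15 0.08 (SE 0.37), Ddb2 -0.08 (SE 0.37) and Perp 0.01 (SE 0.23). The sign of Mdm2 turned when some arrays were left out. The count adjusted over the list alone was 4 without vehicle 1, 0 without vehicle 2, 0 without vehicle 3, 1 without DMBA 2 and 1 without DMBA 3, while the list itself stayed called without each array in turn. With the percent of probes above background on each array as a covariate, the median was 0.27 and the list was no longer called (adjusted p = 0.139).

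**Figure D1:**
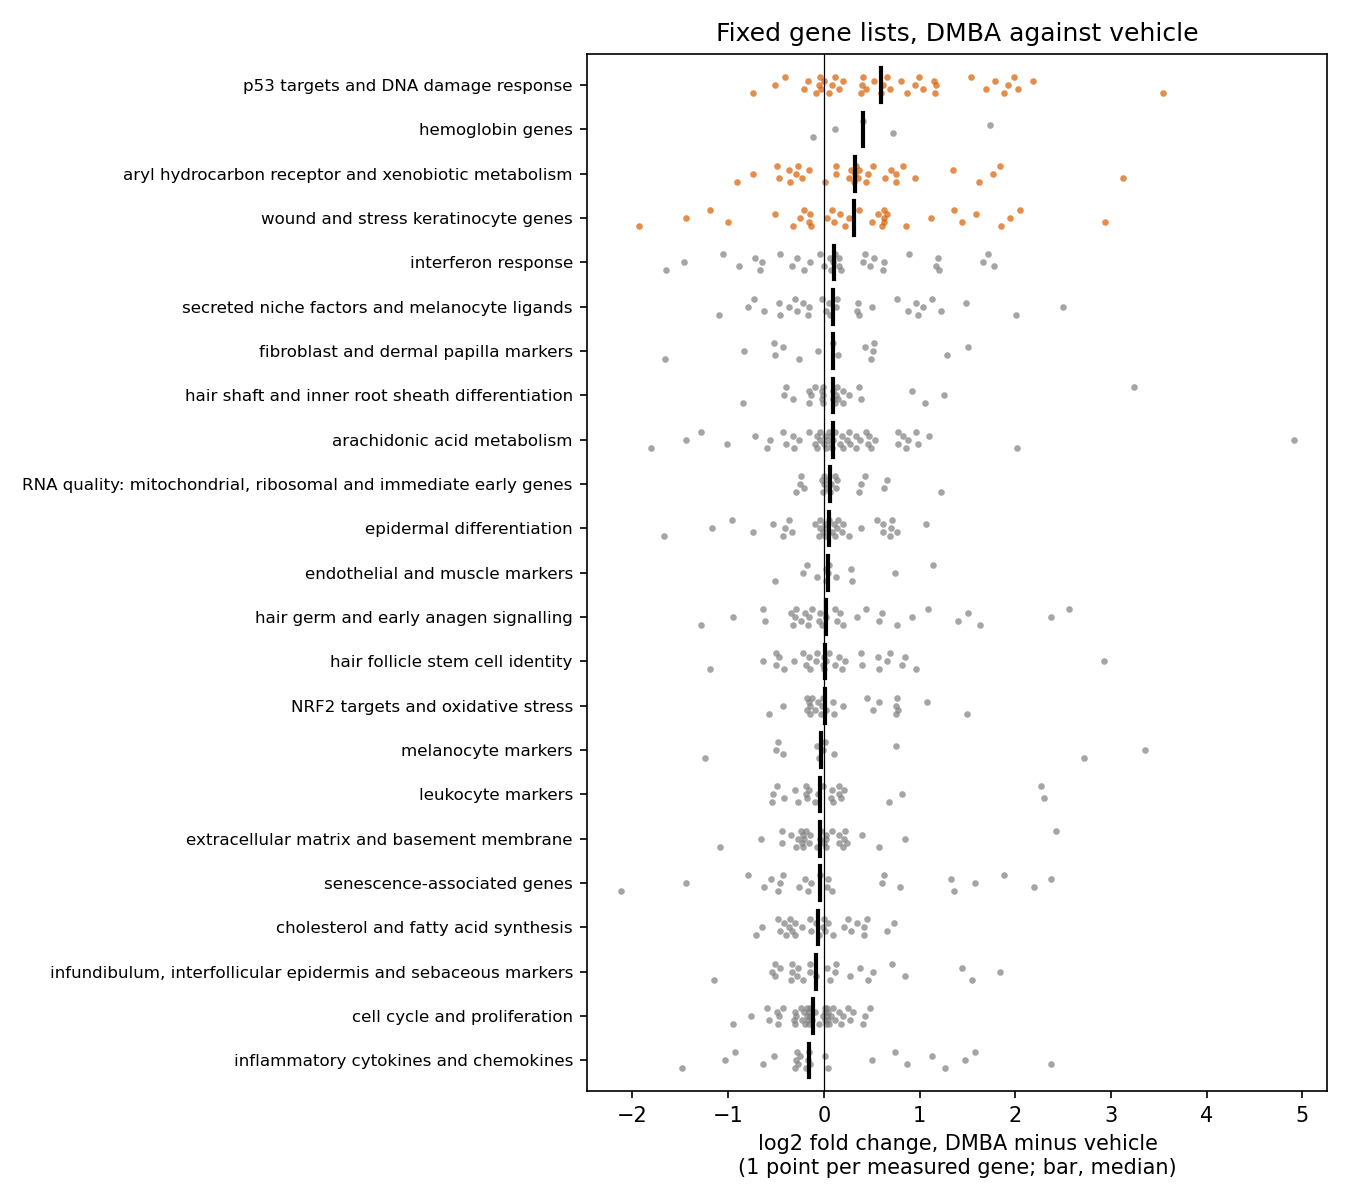
Log2 fold change of each measured gene (points; x axis, DMBA minus vehicle) in each of the 23 fixed gene lists (rows, ordered by median; bars mark medians), with the 3 lists called by camera at the preset correlation in orange. The p53 list has the highest median, 0.60, and the list of inflammatory cytokines the lowest, -0.16.

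Keratinocyte genes of wounding and stress also rose as a set, with 23 of 34 measured members higher, 11 lower and a median log2 fold change of 0.31 (camera adjusted p = 0.0151; adjusted p = 0.434 with an estimated correlation). The mean over the list, relative to the vehicle arrays, did not separate the groups, with 0.37 on vehicle 2 against 0.34 on DMBA 3. When adjusted over the list alone, 2 members passed, Krt6a (1.94, SE 0.37) and Krt6b (1.44, SE 0.29; 3.68 on a dimmer probe), and 0 passed over all genes. Krt16, the keratin that pairs with them, had a value of 2.94 (SE 0.76), the cornified envelope gene Sprr1b 1.85 and the protease inhibitor gene Stfa1 2.05, and none of these passed. Krt17, which basal follicle cells express at rest, had a value of -0.14, and S100a9, an alarmin of inflamed epidermis, -1.93 (SE 1.41). The list's call was lost without vehicle 3 (adjusted p = 0.0781), without DMBA 2 (0.0554) and without DMBA 3 (0.0844), and the count adjusted over the list alone was 0 without vehicle 2, vehicle 3, DMBA 2 or DMBA 3. It was also lost without the filter on dim probes (adjusted p = 0.233).

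The list of aryl hydrocarbon receptor and xenobiotic metabolism genes, which handle compounds such as DMBA, passed narrowly (24 of 34 measured genes higher, 10 lower; median 0.33; camera adjusted p = 0.0441, and adjusted p = 0.384 with an estimated correlation). None of its members passed over all genes or when adjusted over the list alone (0 in each case). Its largest value was that of Aldh1a3, a retinaldehyde dehydrogenase, with a log2 fold change of 3.13 (SE 0.74). Aldh1a3 was not well above background on any vehicle array. Its bound, which leaves out the spread between arrays, was at least 6.01-fold higher after DMBA. The glutathione transferase genes Mgst2 and Gsta3 had values of 1.62 (SE 0.40) and 1.77 (SE 0.60), and the quinone reductase Nqo1 0.75 (SE 0.31). Cyp1b1, which activates DMBA, had a value of 0.37 (SE 0.44), Cyp1a2 0.36 (SE 0.35), Aldh3a1 0.31 (SE 0.29) and Tiparp -0.91 (SE 0.26). Cyp1a1 was well above background on 2 vehicle arrays and 0 DMBA arrays and was not tested. The list's call was lost without vehicle 1 (adjusted p = 0.0747), vehicle 3 (0.0781), DMBA 1 (0.0786), DMBA 2 (0.118) or DMBA 3 (0.111).

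**Figure D2:**
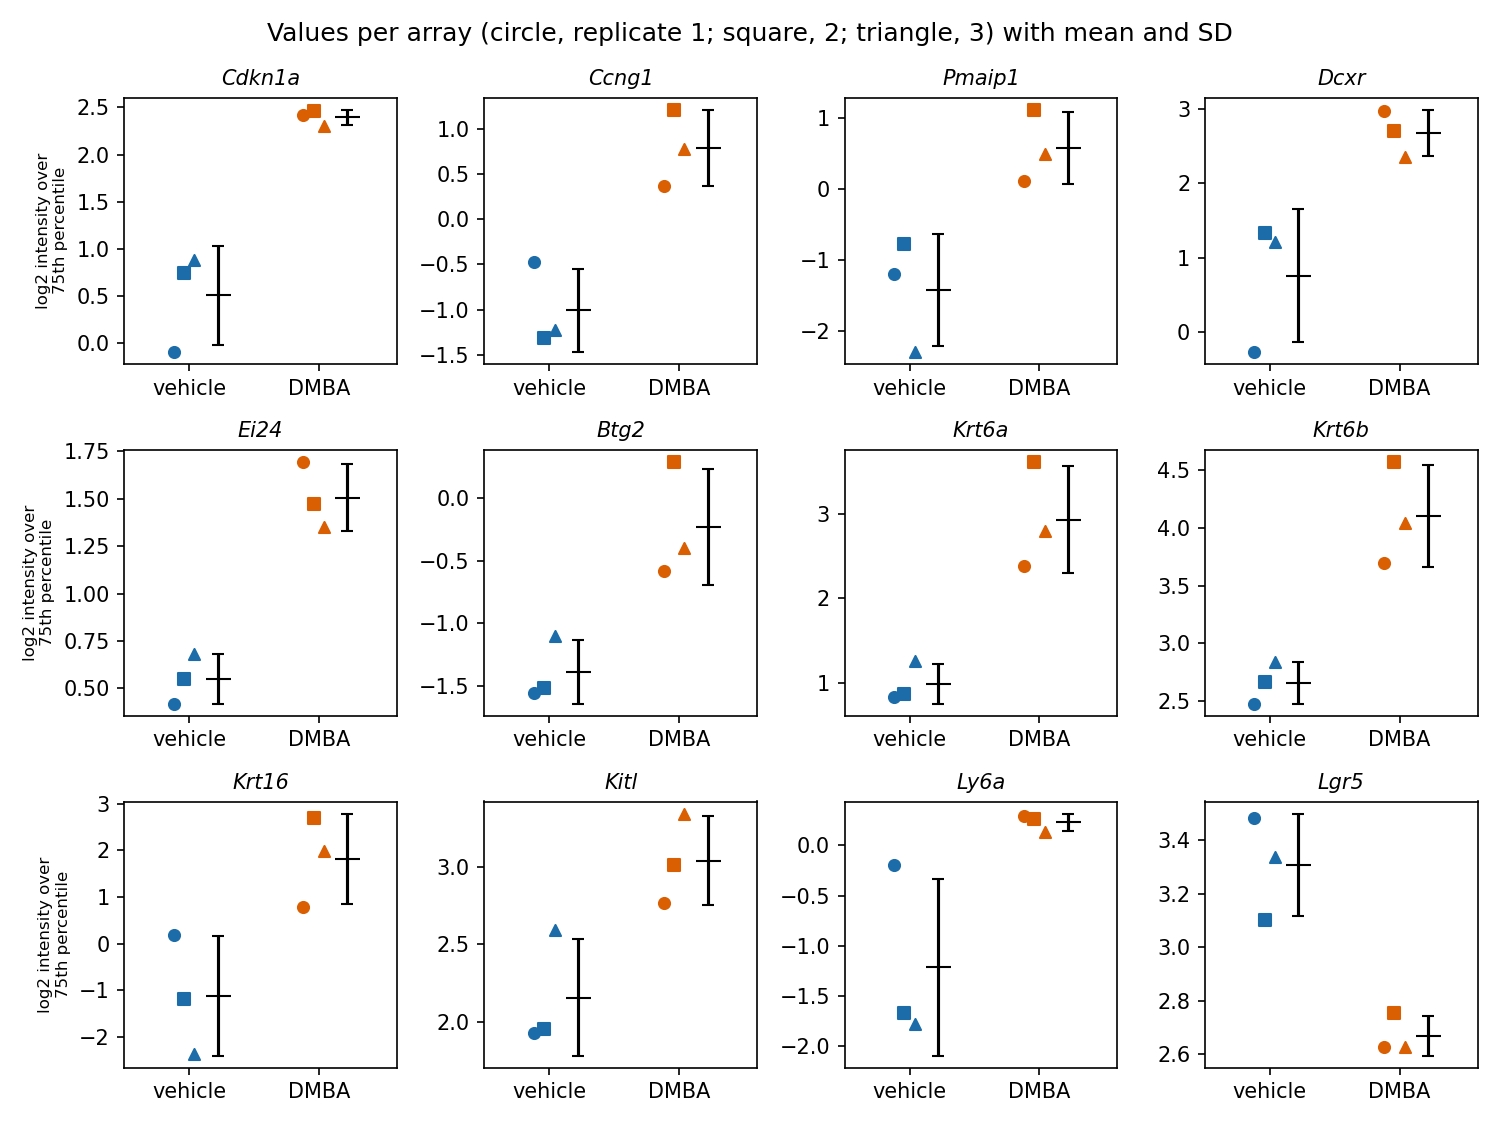
Log2 intensity relative to the array's 75th percentile (y axis, own range in each panel) of 12 genes on the 3 vehicle arrays (blue) and the 3 DMBA arrays (orange), with the group mean and SD as black bars. The DMBA values of Cdkn1a, with a mean of 2.39, lie above the vehicle values, with a mean of 0.51, and those of Lgr5, with a mean of 2.67, below the vehicle values, with a mean of 3.31.

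Among secreted niche factors and melanocyte ligands, 19 of 32 measured genes were higher and 13 lower, the median was 0.10 and the list was not called (adjusted p = 0.328). Kitl lay at 2.16 ± 0.37 (SD, n = 3) in vehicle and 3.04 ± 0.29 in DMBA. All 3 DMBA arrays lay above all 3 vehicle arrays, and the log2 fold change was 0.88 (SE 0.29). It did not pass over all genes (adjusted p = 0.880) or when adjusted over the list alone (adjusted p = 0.178), and it was 0.57 with the percent of probes above background as a covariate. The growth factors Tgfb1 and Bmp2 had values of 2.01 (SE 0.61) and 1.49 (SE 0.49) and the endothelin Edn2 -1.10 (SE 0.32). Tgfb2 had a value of 0.36 (SE 0.40; 1.59 on its other probe). Edn3, the endothelin that acts on melanocytes, was not well above background on any array. In the list of arachidonic acid metabolism, 33 of 52 genes were higher and 19 lower (median 0.09, adjusted p = 0.193). Gpx3, a secreted glutathione peroxidase that was well above background on 1 vehicle array and 3 DMBA arrays, had the largest value, 4.91 (SE 0.77). It was the 1 member that passed when adjusted over the list alone (adjusted p = 0.0307). Faah, which degrades anandamide, had a value of -1.80 (SE 0.49). Ptgs2, the inducible cyclooxygenase, was well above background on 1 DMBA array and 0 vehicle arrays and was not tested.

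The lists of stem cell and hair germ identity had medians near 0, with members that went both ways, and the hair germ list passed fry's mixed test as given above. The list of hair follicle stem cell identity had a median of 0.01 over 32 genes, 17 of them higher (adjusted p = 0.673). Cd34, the classical bulge marker, had a value of -0.01 (SE 0.39), with a turned sign on its other probe. Lgr5, a marker of bulge and hair germ stem cells, had a value of -0.64 (SE 0.22), and the Wnt inhibitor Wif1 2.93 (SE 0.78). In the list of hair germ and early anagen signalling, 17 of 33 genes were higher (median 0.03, adjusted p = 0.328). Axin2, a target of Wnt signalling, passed when adjusted over the list alone (2.37, SE 0.29, adjusted p = 0.00498). Its other probe gave 0.39. Hey1, a Notch target, had a value of 2.56 (SE 0.72). Of the hair shaft and inner root sheath genes, 15 of 28 were higher (median 0.095, adjusted p = 0.328). Tchh, which encodes trichohyalin and was well above background on 1 vehicle array and 3 DMBA arrays, passed when adjusted over the list alone (3.24, SE 0.60, adjusted p = 0.0389). Krtap8-1 had a value of 1.06 (SE 0.34).

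The other keratinocyte programmes were not called by camera over all 6 arrays without a block or covariate, while the NRF2 and senescence lists passed fry's mixed test. The list of epidermal differentiation had a median of 0.05 (21 of 35 genes higher, adjusted p = 0.910), with Klk5 and Lce1b, genes of the outer epidermis, at -0.96 (SE 0.35) and -1.67 (SE 0.61). It was called as higher without vehicle 2 (median 0.23, adjusted p = 0.0477; from 0.0477 to 0.979 over the alternatives). The list of cell cycle genes had a median of -0.11 (27 of 48 lower, adjusted p = 0.328), with the proliferation marker Mki67 at -0.76 (SE 0.54; -0.13 without DMBA 1) and the mitotic genes Bub1 and Nusap1 at -0.59 (SE 0.22) and -0.47 (SE 0.21). It was called as lower with slide as a block, which equals leaving out vehicle 1 (median -0.16, adjusted p = 0.0476), and with the percent of probes above background as a covariate (median -0.18, adjusted p = 0.00336). Over the alternatives its adjusted p ranged from 0.00336 to 0.986. NRF2 targets and oxidative stress genes had a median of 0.01 and a camera adjusted p of 0.133, with 5 members higher at unadjusted p, among them Hmox1, a heme oxygenase (1.08, SE 0.27; its other probe had the opposite sign), and the metallothionein Mt2 (0.76, SE 0.23). The interferon list had a median of 0.11 (adjusted p = 0.328), with Irf9 at 1.17 (SE 0.25) and Xaf1 at 1.71 (SE 0.82). For the inflammatory list the median was -0.16 but the mean 0.14 and the test's direction up (adjusted p = 0.968), with Cxcl1, a neutrophil chemokine, at 2.37 (SE 0.88) and Csf1 at 1.48 (SE 0.58; 2 other probes had the opposite sign). The senescence list likewise had a median of -0.04 and a mean of 0.21 (adjusted p = 0.929). Its members include Cdkn1a and Igfbp3, the latter with a value of -2.12 (SE 0.71). Basement membrane and matrix genes had a median of -0.04, a mean of 0.01 and direction down (adjusted p = 0.930), with Col4a6 at -1.09 (SE 0.42; opposite on its other probe) and Fras1 at 0.85 (SE 0.38). The cholesterol and fatty acid synthesis list had a median of -0.07 (adjusted p = 0.353), with Elovl6, a fatty acid elongase, at -0.65 (SE 0.28).

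Markers of other cells were not called by camera over all 6 arrays either, while the fibroblast list passed fry's mixed test (adjusted p = 0.00210). Ly6a, the gene of the Sca1 antigen that the gate excluded at the cell surface, lay at -1.22 ± 0.88 (SD, n = 3) in vehicle and 0.23 ± 0.09 in DMBA, a log2 fold change of 1.45 (SE 0.45) that did not pass over all genes. The list it belongs to, of infundibulum, interfollicular epidermis and sebaceous gland, had a median of -0.08 and a mean of 0.11 (adjusted p = 0.968), with the sterol acyltransferase Soat1 at -1.14 (SE 0.48). Melanocyte markers had a median of -0.03 and a mean of 0.35 (adjusted p = 0.673). Of the 12 measured, 5 were higher and 7 lower. At unadjusted p under 0.05 in limma, 3 were higher and 0 lower, where 5.23% of all genes passed in either direction. Mlana and Tyrp1, genes of pigment granules, had values of 2.72 (SE 0.95) and 3.35 (SE 1.32) with overlapping groups, Tyrp1 being well above background on 1 vehicle array, and Dct, Mitf and Pmel had values of -0.05, -0.08 and -0.47. Leukocyte markers had a median of -0.04 and a mean of 0.15 (adjusted p = 0.910). H2-Eb1, an MHC class II gene, passed when adjusted over the list alone (2.30, SE 0.45, adjusted p = 0.0463), and H2-Aa, which encodes the alpha chain of another class II molecule, had a value of -0.49 (SE 0.23). Fibroblast and dermal papilla markers had a median of 0.10 (adjusted p = 0.929). Of these Dcn, the proteoglycan decorin, passed when adjusted over the list alone (1.51, SE 0.25, adjusted p = 0.0120), and Col6a2 had a value of -1.66 (SE 0.45). Endothelial and muscle markers had a median of 0.05 (adjusted p = 0.673), with Eng at 1.14 (SE 0.57; 0.50 without DMBA 3) and Pecam1 at -0.51 (SE 0.34). The hemoglobin list had a median of 0.41 over 5 genes (adjusted p = 0.367), with Alas2 at 1.74 (SE 1.05) and Hba-a2 at 0.41 (SE 0.44). When each array was left out these ranged from 0.74 to 2.39 and from 0.043 to 0.72, lowest in each case without vehicle 3. The hemoglobin list was called as higher with the covariate (median 1.11, adjusted p = 0.00158; from 0.00158 to 0.986 over the alternatives). The list of RNA quality genes had a median of 0.07 (adjusted p = 0.328), with the immediate early genes Ier2 at 1.23 (SE 0.42) and Fosb at 0.63 (SE 0.29).

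The genes of smallest p in each direction missed the threshold and are given as values (adjusted p = 0.438 for each of the 14 higher genes). On the higher side Sectm1b had a log2 fold change of 1.86 (SE 0.23), Ms4a10 3.19 (SE 0.42), Mettl22 2.68 (SE 0.35), the protease inhibitor Serpine2 2.73 (SE 0.41), and Prodh, the first enzyme of proline breakdown, 2.35 (SE 0.32). Rln1, a relaxin, had a value of 4.61 (SE 0.67), Slc19a2, a thiamine transporter, 1.74 (SE 0.27), Cdnf 1.76 (SE 0.26), Galm, a galactose mutarotase, 1.70 (SE 0.25) and the taste receptor gene Tas2r122 1.72 (SE 0.26). Cd274, which encodes the immune checkpoint ligand PD-L1, and the acute phase gene Serpina3n had values of 4.29 (SE 0.63) and 4.87 (SE 0.73). Neither was well above background on any vehicle array. Their bounds, which leave out the spread between arrays, were at least 7.58-fold and at least 10.8-fold higher after DMBA. Axin2 and Gpx3 complete this group. On the lower side St3gal5, the synthase of the ganglioside GM3, had a value of -2.26 (SE 0.40), Chil1, a chitinase-like protein, -3.01 (SE 0.47), Dock9 -2.15 (SE 0.33), and Mansc4 -4.17 (SE 0.70). Swt1, well above background on 1 DMBA array, had a value of -2.99 (SE 0.46), Ccdc88a -1.82 (SE 0.33), Xlr3b -3.12 (SE 0.53), Zfp39 -1.30 (SE 0.23), Tmem98 -1.30 (SE 0.21) and the deacetylase Hdac10 -1.18 (SE 0.21). Tnfsf11, which encodes the cytokine RANKL, Cep72, Ric3 and Unc93a had values of -2.79 (SE 0.45), -2.37 (SE 0.325), -2.18 (SE 0.27) and -2.54 (SE 0.31). None of them was well above background on any DMBA array. Their bounds of the same kind were at least 1.98-fold, 2.26-fold, 1.79-fold and 2.31-fold lower there. By mean signal, 8 of the 14 higher genes and 9 of the 14 lower genes belonged to the dimmest of 3 equal groups of genes, and 0 and 1 to the brightest.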

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

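Most alternative analyses were fixed before the data were examined. Chosen after seeing them were a filter on the mean signal relative to the 75th percentile, vehicle 1 and DMBA 1 left out together, the percent of probes above background as a covariate, genes with probes over 16-fold apart left out, and features without a symbol included. The cause of the differences below was not tested.

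The count of genes past the threshold was 0 in 25 of 26 alternatives and ranged from 0 to 1 when each array was left out. With features without a symbol included it was 0 of 30429 in limma, with 1443 at unadjusted p under 0.05. Genes higher at unadjusted p numbered 1259 without a filter, where 455 of the 21354 genes tested were lower, and 756 with the covariate. Chance alone gives a share of 0.05 over both directions. Without a filter, probes near the floor are tested too, and the lowest values were higher on the DMBA arrays. Genes lower at unadjusted p numbered 675 with array weights and 689 without vehicle 1 and DMBA 1, and ranged from 397 to 728 when each array was left out. Kitl kept its direction in 22 alternatives, from 0.57 to 1.098, and passed in none of them. Since it has 1 probe, its value had to stay at 0.88 with the filters, the mean of kept probes, the trend and the replicate block. Its groups do not overlap, so leaving out an array could not turn its sign. Of 1690 values of 79 named genes, 1673 kept direction and side of the threshold and 0 passed. Some alternatives leave a gene's value unchanged, so this count does not measure robustness. Signs turned in 7 genes. Cd34 was 0.037 with the mean of kept probes, 0.26 with the slide block, 0.0041 without vehicle 1 and DMBA 1, 0.46 with the covariate, and from -0.26 to 0.27 when each array was left out. Csf1 was -0.31 with the mean of kept probes. Mdm2 was -0.30 with the covariate and from -0.037 to 0.53 when each array was left out. In the same leave-one-out fits Cyp1b1 ranged from -0.042 to 0.79, Tgfb2 from -0.00038 to 0.62, Itga6 from -0.43 to 0.095 and Krt15 from -0.047 to 0.33. Without vehicle 1 and DMBA 1, Itga6 was 0.067 and Krt15 -0.10.

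The replicate numbers did not pair the samples: arrays with the same number had correlations of their deviations of 0.018, -0.020 and 0.058. With the replicate block the count of genes was 0, p53 list members past the list alone numbered 0 and those of the wound list 0, and no list lost its call. With the slide block, which leaves the comparison to the other 5 arrays, p53 list members numbered 4. They numbered 4 without vehicle 1 and DMBA 1, 0 with the covariate, and from 0 to 9 when each array was left out. Wound list members numbered 4 with normexp and array weights, 1 with the covariate, 0 with quantile, loess, the filters at no and at least 1 array, the mean of kept probes and the genes with probes over 16-fold apart left out, and from 0 to 3 when each array was left out. The number of lists called was 1 without a filter, 1 with the filter at 1 array and 1 without vehicle 1 and DMBA 1. It was 0 with an estimated correlation and 0 with the directional form of fry (8 with its mixed form). When each array was left out it ranged from 1 to 4.

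The p53 list kept its call in 21 of 24 alternatives, with medians from 0.41 to 0.76 when each array was left out (highest adjusted p = 0.000165). The p53 list lost its call with an estimated correlation (median 0.60), with fry (0.60) and with the covariate (0.27). The 21 are not independent and all used camera's preset correlation. Camera does not use the intensity trend, and the slide block repeats the fit without vehicle 1. The same repeats enter the counts of the wound and xenobiotic lists. The wound list lost its call in 8 of 24: no filter (median 0.19), filter at 1 array (0.19), vehicle 1 and DMBA 1 out (0.21), estimated correlation (0.31), fry (0.31) and 3 of the leave-one-out fits. Over all 6 leave-one-out fits its medians ranged from 0.16 to 0.42. The xenobiotic list lost it in 17 of 24: normexp (0.24), no filter (0.31), filter at all arrays (0.30), filter at 1 array (0.31), mean of kept probes (0.33), array weights (0.29), slide block (0.21), estimated correlation (0.33), fry (0.33), filter on mean signal (0.13), vehicle 1 and DMBA 1 out (0.26), covariate (0.31) and 5 leave-one-out fits (from 0.20 to 0.33).

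Lists not called in the report changed as follows, by median. The cell cycle list was called as lower with the slide block and without vehicle 1 (-0.16, adjusted p = 0.0476) and with the covariate (-0.18, adjusted p = 0.00336), the hemoglobin list as higher with the covariate (1.11, adjusted p = 0.00158) and the epidermal differentiation list as higher without vehicle 2 (adjusted p = 0.0477). The test's direction turned for epidermal differentiation with normexp (0.0081), array weights (-0.0022), slide block (-0.028) and both first arrays out (-0.098). It turned for senescence with normexp (-0.13), filter at all arrays (-0.13), slide block (-0.12) and covariate (-0.16). The infundibulum list turned with normexp (-0.094), quantile (-0.093), loess (-0.074), no filter (-0.077), filter at all arrays (-0.14), fry (-0.077) and filter on mean signal (-0.14). It turned for the inflammatory list with quantile (-0.17), loess (-0.18), filter at 1 array (-0.082), mean of kept probes (-0.16), fry (-0.16) and covariate (-0.028). The matrix list turned with quantile (-0.046), filter at 1 array (-0.035), array weights (-0.046), filter on mean signal (-0.044) and both first arrays out (-0.0047). Leukocyte markers turned with no filter (-0.037), array weights (-0.13), slide block (-0.058) and both first arrays out (-0.22), fibroblast markers with array weights (-0.17) and both first arrays out (-0.18), and stem cell identity with the slide block (0.0049) and covariate (0.060). In leave-one-out fits the medians of the lists whose direction turned in at least 1 fit ranged from -0.038 to 0.23 for epidermal differentiation, -0.12 to 0.0038 for senescence, -0.21 to 0.18 for the infundibulum list, -0.23 to -0.067 for the inflammatory list, -0.19 to 0.037 for the matrix list, -0.15 to 0.15 for leukocytes, -0.33 to 0.17 for fibroblasts, -0.040 to 0.065 for stem cell identity, -0.16 to 0.033 for the cell cycle, -0.063 to 0.16 for endothelium and muscle and -0.11 to 0.72 for hemoglobin.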

Other observations

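Prodh and Slc19a2, which are known as p53 targets outside the list and were singled out after their values were seen, had log2 fold changes of 2.35 (SE 0.32) and 1.74 (SE 0.27), and in each the 3 DMBA arrays lay above the 3 vehicle arrays. Neither passed over all genes (adjusted p = 0.438). Within the list Cdkn1a had a value of 1.88, Mdm2 0.16, Bax 0.12 and Perp 0.01. The mean over the list, relative to the vehicle arrays, was 0.50 on DMBA 1, 1.00 on DMBA 2 and 0.68 on DMBA 3, and lay between -0.04 and 0.03 on the vehicle arrays. This mean separated the groups in 6 of the 23 lists, where chance alone gives 10%, and 4 of the 6 were not called by camera. The lists share some genes and all use the same arrays, so their separations are not independent and this count is no test. In the wound list, which was called, it did not, with 0.37 on vehicle 2 against 0.34 on DMBA 3.

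Of the MHC class II genes, whose values were looked at after that of H2-Eb1 was seen, H2-Eb1 had a log2 fold change of 2.30 (SE 0.45), H2-Aa -0.49 (SE 0.23), H2-Ab1 -0.01 (SE 0.42) and the invariant chain Cd74 -0.54 (SE 0.72). None of them passed over all genes.

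For the patterns below, the tests of gene counts and camera p over other splits were set before their results were seen. So was the test with epidermal markers. The tests with the brightest genes, dimmer epidermal markers, single arrays, the covariate and markers of leukocytes, fibroblasts and endothelium were chosen after the result was seen. Fry in its mixed form was planned for the real groups, but its use over other splits was chosen later. For single arrays the leave-one-out fits themselves were planned, and only their limit as a test was set later.

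The first pattern is the count of 0 genes past the threshold. Noise of dim probes stays open as a cause: the 5945 genes of the brightest group gave 0 calls when tested alone with limma (smallest adjusted p = 0.298). The test recovered only 0.597% of simulated 2-fold changes over all genes. Recovery among the brightest genes alone, whose spread is smaller, was not simulated, so their 0 calls cannot decide. These genes had 348 at unadjusted p under 0.05 when tested alone against 178 when tested with the dimmer genes. Chance alone gives a share of 0.05 of them, which lies between these counts. The fold changes are the same in both fits, and only the spread that eBayes borrows from other genes differs. The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05: the real split gave 933 genes at unadjusted p under 0.05, 4 of the 10 splits gave at least as many, and the highest other split gave 1347. Camera called 3 lists in the real split and also 3 in the highest other, fry in its mixed form 8 and 1, and the split with 1347 genes sets vehicle 1, vehicle 2 and DMBA 1, the arrays with the largest shares of probes above background, against the other 3.

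The second pattern is the rise of the p53 list. A single array, or the slide that holds vehicle 1 alone, is argued against only by the medians, the lowest over the leave-one-out fits being 0.41. Camera's adjusted p was under the threshold in each fit, but this adds little. Splits that mix the groups also gave the list a camera p of 4.29e-07, 2.07e-05 and 3.32e-05 at the preset correlation. The strength of the arrays stays open: with the percent of probes above background as a covariate the median was 0.27, the list mean went from 0.73 (SE 0.15) to 0.53 (SE 0.13) and the call ended as the estimate became smaller, but the covariate shares 0.402 of its variance with the groups, so treatment and signal cannot be told apart fully. Fibroblasts in the sort, which the gate would remove, stay open as a possible source, since the lower 95% bootstrap bound of the p53 median minus the fibroblast median was -0.069, whereas it was 0.23 for leukocytes and 0.12 for endothelium and muscle. These bounds resample the genes of a single fit and leave out the spread between arrays, so they cannot exclude leukocytes or endothelium. Among the 10 splits, too few for a share under 0.05, 1 gave a camera p as small, the real one, with -log10 p of 9.79 against 6.37 for the highest other, the same split by share of probes above background.

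The third pattern is the set of higher values of Krt6a, Krt6b and Krt16. A larger share of epidermal or infundibular cells is argued against as the whole cause only by the bright members of those lists. The 39 members brighter than the arrays' 75th percentile had a median log2 fold change of 0.01 with an upper 95% bootstrap bound of 0.11. The limit was 0.72, by a rule set before the result was seen that starts from the smallest keratin change. The bounds resample the genes of a single fit and leave out the spread between arrays, and a high baseline could hide an added share. The 20 dimmer members, where a high baseline would hide less, came much closer to that limit, with a median of 0.44 and bounds of -0.31 and 0.70, and among them Ly6a, whose antigen the gate excluded, had a value of 1.45 (SE 0.45) and Soat1 -1.14 (SE 0.48). A part played by such cells, or a change of state within the sorted cells, therefore stays open. Of the 10 splits, too few for a share under 0.05, 1 gave a camera p for the wound list as small, the real one, with -log10 p of 2.88 against 2.44 for the highest other.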
